A study of Mus musculus with 8 samples.

How the data were processed

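The series holds 8 samples of 1 organism, the mouse, each a pool of sorted Gfp-positive cells from the ventral midbrain of E14.5 embryos. Per the labels, the tissue was parted into rostral and caudal, each pool came from 5 to 7 embryos, and specimens of several litters were spread over the pools. The groups, 4 rostral and 4 caudal pools, were taken from the labels. Each array has 2 channels: per the labels, Cy3 (green) holds the sorted sample and Cy5 (red) holds a common reference made of Gfp-negative cells, on every array, so dyes were not swapped.

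The scanner files hold raw spot intensities, made by the authors with Agilent Feature Extraction 10.7.3.1, per the file headers. These are median pixel intensities of the spot and of its local background in each channel, with no normalization. The same files hold processed intensities, which per the file headers were background-subtracted, spatially detrended and dye-normalized by lowess. Other columns of the deposited files mark, as 0 or 1 per spot, whether it is well above background, saturated or an outlier. All 8 arrays lie on 1 slide and share 1 scan. RMA is named in the submitters' processing notes with no version or role. A deposited table of the whole series has 8 columns of values whose names match no sample label, so those 8 columns were not used, and only its probe annotation was. An aligner does not apply to arrays, and the build behind the array design was used for no coordinate, so none is printed.

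Analysis was done in R 4.3.3 with limma 3.58.1; files were read with data.table, version 1.17.8. The plan, with the lists and the rule for named genes, was fixed before the data were examined. It named mean spot signals, but the files hold median signals, which were used in their place. Background was corrected with normexp (offset 50) over all spots, and each array was normalized by loess with control spots and outlier spots at weight 0. The log2 ratio of green over red is thus the level in sorted cells relative to the reference. Each array has 62976 spots, 59305 of them not controls. Spots of 1 probe were averaged, leaving out the 210 to 298 spots per array marked as outliers, and saturated spots were kept (0 in green, at most 2 in red).

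Of 55681 probes, 27528 were named by their accession through a RefSeq gene table (assembly GRCm38.p6), 4105 by the symbol of the annotated table, and 24048 stayed unnamed. That table lists 37850 probes, and 5792 of the probes named by accession are not in it. The named probes hold 23912 symbols, of which 6263 have 2 or more probes; the probe with the highest mean brightness over the 8 arrays stands for its gene. For rostral against caudal, a gene was tested if its probe was well above background in the sample channel on at least 4 of 8 arrays. For Gfp-positive against Gfp-negative cells, either channel sufficed. Between 62.5% and 70.4% of probes were well above background in green and 54.0% to 63.5% in red. A gene not well above background on any array of a group has only a bound there. It is given as "at least N-fold": the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own, per channel after loess and Aquantile, and open to dye bias.

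Changes were tested with limma (lmFit, then eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method; a gene changed if its adjusted p was below 0.05. The first contrast was the mean ratio over the 8 pools against 0, in which the reference is 1 control sample. The second was rostral minus caudal, with no block. All p-values of genes and lists in the report are 2-sided and from limma.

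There were 15 pathway and region lists: dopamine synthesis, transport and storage; midbrain dopaminergic transcription factors; substantia nigra associated; ventral tegmental area associated; diencephalic and rostral; isthmic and caudal; retinoic acid; Wnt pathway; axon guidance and migration; Parkinson's disease; oxidative phosphorylation; neuropeptides; calcium binding and calcium channels; synaptic vesicles and neuronal maturation; and cell cycle. The 12 marker lists were pan-neuronal, progenitor and radial glia, GABAergic, glutamatergic and red nucleus, motor and oculomotor, serotonergic, oligodendrocyte precursor, microglia, endothelial, pericyte and mesenchyme, erythroid, and dissociation stress. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes, with the intensity trend, and adjusted over the 27 lists. Camera with an estimated correlation and fry were run beside it. Counts of list members are given over all genes tested and adjusted over the list alone.

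The text names, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among changed genes with a named symbol whose arrays did not overlap, up to 4 members of each list with the smallest p, and 15 genes of dopaminergic neurons chosen beforehand. Not all of them are printed, and some are not reported here; Kcnj6, 1 of the 15, was too dim to be tested. The pattern that sets clone-like names aside was written after the top genes had been seen. Genes named outside this rule are marked as chosen after their values were seen.

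The scripts were tested on simulated data with 200 genes changed by known amounts, on independent random noise with each probe's spread between these arrays. For rostral against caudal (18099 genes), 34.3% of genes changed by 0.5 on the log2 scale, 71.6% of those changed by 1 and 90.9% of those changed by 2 were called, with 6 of 17899 unchanged genes. For the Gfp comparison (18602 genes) the shares were 67.2%, 91.0% and 100%, with 9 of 18402 unchanged genes. In the data 1145 and 13287 genes were called in these comparisons, far more than the 200 simulated. These shares and false calls thus need not carry over to the data. A list moved by 0.3 was called in both and 0 of 26 unmoved lists were called by camera. The noise of each gene was simulated independently, so these list results cannot test camera's preset correlation between genes.

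Alternatives fixed beforehand were: no background subtraction, Feature Extraction processed signals, Aquantile between arrays, the sample channel alone, other filters on dim probes, the mean of a gene's probes or each probe alone, the replicate number as a block, the slide row as a block, array weights, no trend in the variance prior, a minimum change of 1 on the log2 scale, leaving out each array, and other set tests. Within-row fits, camera without a trend, and list tests with the slide row as a block or on the sample channel alone were added after seeing the data.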

Results

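Gene expression was measured in dopaminergic neurons of the mouse midbrain at day E14.5. The embryos carried a Gfp reporter at the locus of Pitx3, a transcription factor gene whose expression in the brain marks midbrain dopaminergic neurons. The ventral midbrain was parted into a rostral and a caudal piece, the tissue was dissociated with papain, and Gfp-positive cells were collected by cell sorting. There were 4 rostral and 4 caudal pools, each from 5 to 7 embryos. Each pool was labelled with Cy3 and hybridised on a 2-colour Agilent array against a common reference in Cy5, a pool of Gfp-negative cells of the same specimens. Of 55681 non-control probes, 62.5% to 70.4% were well above background in the sample channel and 54.0% to 63.5% in the reference channel. The log2 ratios of any 2 arrays correlated across genes at 0.81 to 0.91, genes not being independent replicates. The first principal component held 32.2% of the variance and separated the 2 parts. The p-values measure the spread between these pools, and the number of arrays limits the precision.

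The first comparison set the Gfp-positive cells of both parts against the Gfp-negative reference and asked which transcripts mark the sorted neurons. Several genes of dopamine handling stood far above the reference. Slc6a3, the dopamine transporter, was 63.0-fold higher in Gfp-positive cells (log2 ratio 5.98, SE 0.04, n = 8 pools), Slc18a2, the vesicular monoamine transporter, 30.7-fold higher (4.94, SE 0.05), and Th, the rate-limiting enzyme of dopamine synthesis, 10.1-fold higher (3.34, SE 0.03). Hba-a2, an alpha globin of red blood cells, was 49.7-fold lower (-5.64, SE 0.06), Pou4f2, a transcription factor gene of glutamatergic neurons, 48.2-fold lower (-5.59, SE 0.13), and Fabp7, a gene of radial glia, 29.0-fold lower (-4.86, SE 0.08). Pitx3 itself was 12.0-fold higher (3.58, SE 0.04), which only checks the sort. Of 18602 genes tested, limma called 13287 changed at an adjusted p below 0.05, 6419 higher and 6868 lower in Gfp-positive cells. A change of at least 2-fold was seen for 2429 of them, 621 higher and 1808 lower. Which direction held more called genes depended on the processing, as the Feature Extraction processed signals gave 7284 higher and 6254 lower. All 8 ratios had 1 sign for 9729 genes (52.3%). By chance this would be 0.781% if the 8 signs were independent, which the shared reference and dye do not allow, so the chance share is not known. The reference counts as 1 control sample whose own spread the test leaves out, and it carried the same dye on every array, so any dye effect is part of each ratio.

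The other genes with the largest rises were Chrna6, a nicotinic receptor subunit (55.0-fold), Aldh1a1, a retinaldehyde dehydrogenase (49.5-fold), Ret, the GDNF receptor kinase (log2 4.74), Kcnk9, a potassium channel (4.56), Gch1, which makes the cofactor of Th (17.4-fold), the vasopressin receptor gene Avpr1a (4.08), the transcript annotated as Slc10a4l (4.03) and Slc35d3 (16.0-fold). A second probe of Kcnk9 gave 1.21. Of the 12 tested genes of dopamine synthesis, transport and storage, 7 were higher and 4 lower, with a median of 1.66 (camera adjusted p = 0.0294, and adjusted p = 0.125 with an estimated correlation). Ddc, the enzyme that turns L-DOPA into dopamine, was at 2.24 (SE 0.04), with 4.31 by another probe, and the dopamine receptor gene Drd2 at 2.09 (SE 0.13). The midbrain dopaminergic transcription factors numbered 16, of which 11 were higher and 3 lower (median 1.00, adjusted p = 0.00081, and adjusted p = 0.0893 with an estimated correlation). Foxa1 (3.94), Nr4a2 (3.76), Foxa2 (3.70) and Lmx1a (3.39) were each over 3 on the log2 scale, with SEs of 0.03 to 0.04. En2 was at 1.89 (SE 0.06) and En1 at 2.09 (SE 0.07), the reference being well above background on 6 of 8 arrays for En1, whose ratio was 3.21 in the Feature Extraction processed signals. Otx2 was lower (-1.40, SE 0.16). Among 21 genes associated with Parkinson's disease, 15 were higher and 4 lower (median 0.23, adjusted p = 0.0183, and adjusted p = 0.102 with an estimated correlation). Of these, Uchl1 was at 0.69 (SE 0.03) and Rab29 at -2.64 (SE 0.13).

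Neuronal excitability and release genes were also set apart. Of 18 calcium-binding and voltage-gated calcium channel genes, 15 were higher and 2 lower (median 0.42, adjusted p = 0.00081, and adjusted p = 0.102 with an estimated correlation). Cacna2d3, a channel subunit, was at 2.06 (SE 0.04) and the calcium binding gene Necab1 at 2.42 (SE 0.14), with the reference well above background on 6 of 8 arrays for Necab1. Of 26 genes of synaptic vesicles and neuronal maturation, 17 were higher and 5 lower (median 0.38, adjusted p = 0.0011, and adjusted p = 0.102 with an estimated correlation). Syt4 (1.41) and Stx1a (1.25), both of vesicle release, were among them. Nrxn3, a presynaptic adhesion gene, was 2.84-fold higher, but its probes disagreed, the others giving log2 ratios of -0.18 to 1.04. The probe at -0.18 was well above background in 4 of 8 pools and on 2 of 8 arrays for the reference. Among 12 pan-neuronal markers, 8 were higher and 4 lower (median 0.16, adjusted p = 0.321). Dcx was at 0.82, with 0.36 (adjusted p = 0.022) and 0.41 (adjusted p = 0.0682) by other probes and 0.53 as the mean over probes, and Nsg2 at -1.17, with -0.72 in the Feature Extraction processed signals. Ncam1 was at -0.56, at 0.04 in the Feature Extraction processed signals and at 0.37 and -0.91 by other probes. Axon guidance and migration genes went both ways, 14 higher and 19 lower of 37 (median -0.17, adjusted p = 0.487), and Plxna4, a semaphorin co-receptor, was at 1.45, with 0.44 by another probe. For that other probe the reference was well above background on 1 of 8 arrays.

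Genes of most other cell types lay below the reference. All 24 tested cell cycle genes were lower (median -2.02, adjusted p = 3.4e-10, and adjusted p = 0.0893 with an estimated correlation), including Ccnb1 (-3.46) and Cdk1 (-2.47). Another probe of Ccnb1, well above background in 4 of 8 Gfp-positive pools, gave -1.86. Another probe of Cdk1 gave -0.80 but was well above background in 0 of the 8, so this value does not measure the size of the fall. Progenitor and radial glia markers were lower for 15 of 18 and higher for 1 (median -1.89, adjusted p = 2.35e-05, and adjusted p = 0.125 with an estimated correlation), and the glutamate transporter gene Slc1a3 was at -4.16. All 6 oligodendrocyte precursor markers were lower (median -3.35, adjusted p = 0.00045, and adjusted p = 0.102 with an estimated correlation), Olig1 at -4.41. Of 11 GABAergic markers 9 were lower and 1 higher (median -2.86, adjusted p = 0.00050, and adjusted p = 0.102 with an estimated correlation), among them Tal2 (-4.92) and Gad1, the GABA-synthesising enzyme (-3.50). Glutamatergic and red nucleus markers were lower for 6 of 9 and higher for 1 (median -3.22, adjusted p = 0.0096, and adjusted p = 0.102 with an estimated correlation). Motor and oculomotor markers were lower for 7 of 10 and higher for 1 (median -0.64, adjusted p = 0.0359), and Isl2 was at -3.45 (-5.70 in the Feature Extraction processed signals), measured above background in 2 of 8 Gfp-positive pools. Serotonergic markers were lower for 4 of 6 and higher for 1 (median -1.88, adjusted p = 0.0451), with Fev, a serotonergic transcription factor gene, at -2.30. With an estimated correlation the adjusted p of both of these lists was 0.158. Endothelial markers were lower for 10 of 11 and higher for 0 (median -1.82, adjusted p = 0.00045, and adjusted p = 0.102 with an estimated correlation), Cdh5 at -2.35. Pericyte and mesenchyme markers were lower for 9 of 11 and higher for 1 (median -3.06, adjusted p = 0.0015, and adjusted p = 0.125 with an estimated correlation). Pdgfrb was at -4.72 and Kcnj8 at -4.34, and Rgs5, not well above background in any Gfp-positive pool, was at least 4.63-fold lower. All 12 erythroid markers were lower (median -3.68, adjusted p = 1.1e-05, and adjusted p = 0.125 with an estimated correlation). Among the other large falls were Sparcl1 (-5.43), the chloride channel gene Ano1 (-4.73) and the glial proteoglycan gene Bcan (-4.55, and -2.87 by another probe).

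Regional and signalling genes of the neighbouring tissue were mostly lower as well. Diencephalic and rostral genes were lower for 18 of 21 and higher for 2 (median -2.96, adjusted p = 1.3e-06, and adjusted p = 0.125 with an estimated correlation), among them Irx3 (-3.30) and Nkx2-1 (-2.70). Isthmic and caudal genes were lower for 12 of 17 and higher for 3 (median -0.64, adjusted p = 0.0195), with Etv4, a target of FGF signalling, at -2.69. Wnt pathway genes were lower for 19 of 25 and higher for 3 (median -1.34, adjusted p = 0.00050), yet Rspo3, a secreted Wnt activator, rose (2.72, SE 0.08). With an estimated correlation the adjusted p was 0.102 for the isthmic list and 0.0893 for the Wnt list. Oxidative phosphorylation genes were lower for 24 of 36 and higher for 3 (median -0.23, adjusted p = 0.00081, and adjusted p = 0.193 with an estimated correlation), Atp5b at -1.11 and at -0.73 in the Feature Extraction processed signals. Retinoic acid genes, 13 lower and 4 higher of 18 (median -0.57, adjusted p = 0.0669), included Cyp26b1, which degrades retinoic acid (-4.32), and the retinol carrier Rbp4 (1.97). Camera put this list down and fry up. Neuropeptides were lower for 11 of 16 and higher for 4 (median -0.69, adjusted p = 0.0795), with Npy at -4.02, Sst at -3.53 and Cck at 2.08 (SE 0.16). Dissociation stress markers were lower for 7 of 11 and higher for 0 (median -0.44, adjusted p = 0.0669). Of 15 genes associated with the substantia nigra, 7 were higher and 3 lower (median 0.08, adjusted p = 0.115), and of 18 associated with the ventral tegmental area, 9 were higher and 5 lower (median 0.29, mean -0.04, camera direction up, adjusted p = 0.291), with Crym at -4.28. Neither Lmo3 (0.07, adjusted p = 0.339), Sox6 (-0.10, adjusted p = 0.473) nor Calb1 (-0.23, adjusted p = 0.221) passed the test. Lmo3 passed it in the Feature Extraction processed signals (0.18, adjusted p = 0.0226), and Sox6 without rostral pool 2 (-0.22, adjusted p = 0.032). Another probe of Calb1 gave 0.25 (adjusted p = 0.0473). That probe was well above background in 4 Gfp-positive pools but on 0 arrays for the reference. Its value thus does not measure the size of a change, and its test decides nothing. Sox6 was well above background in 4 rostral and 2 caudal pools. Among 11 microglia markers 1 was higher and 0 were lower (median 0.20, adjusted p = 0.331). That marker was Mrc1, a mannose receptor of macrophages (0.83, SE 0.13), whose ratios did not share 1 sign. Adjusted over the list alone, the counts of all 27 lists were the same but for oxidative phosphorylation, with 4 genes higher. Camera called 19 of 27 lists, 0 with an estimated correlation (11 at an unadjusted p below 0.05), and fry called 24 for net movement in 1 direction. The estimate was below the preset 0.01 for the Wnt list (-0.0093) and the transcription factor list (-0.0094). Yet their unadjusted camera p rose from 0.00015 to 0.0055 and from 0.00031 to 0.0082. For these lists a higher correlation is thus not why the call was lost.

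**Figure D1:**
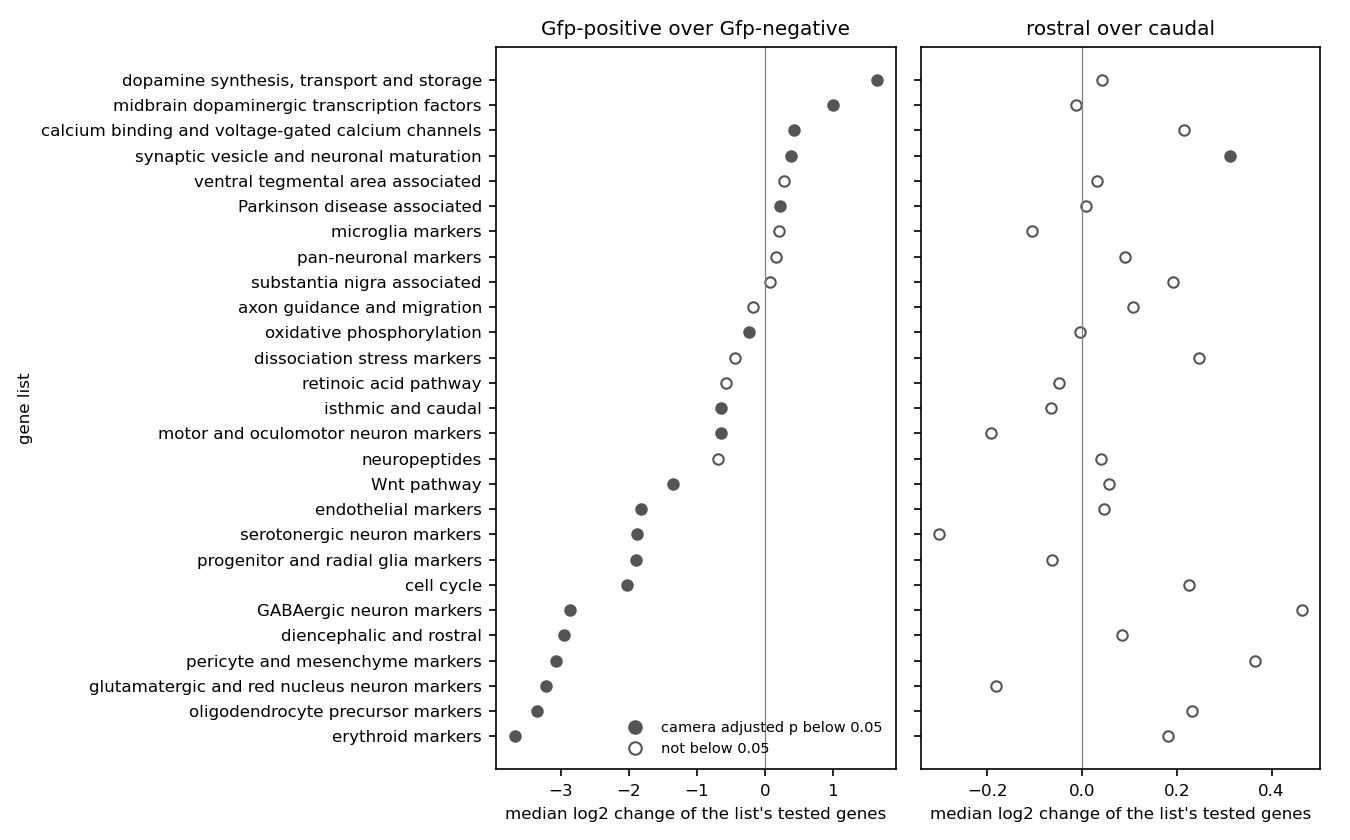
Median log2 change of each of 27 gene lists, for Gfp-positive cells against the Gfp-negative reference (n = 8 pools) and for rostral against caudal pools (n = 4 each); each point is 1 list in 1 comparison, and filled points passed camera at an adjusted p below 0.05. In the first comparison 19 lists are filled, with medians from -3.68 to 1.66, and in the second 1 list, at 0.31.

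The second comparison set rostral against caudal Gfp-positive pools, the contrast through which the series addresses how dopaminergic subsets are specified. The largest change was in the pseudogene Sfta3-ps, which was at least 32.1-fold higher in rostral pools in the sample channel, being not well above background in any caudal pool (fitted log2 change of the ratio 4.96, SE 0.22, n = 4 and 4, adjusted p = 3.2e-05). Nkx2-1, a hypothalamic transcription factor gene, was 4.95-fold higher (2.31, SE 0.13), and Dlx2, of forebrain GABAergic neurons, 8.78-fold (3.13, SE 0.30). In caudal pools Evx1, an interneuron homeobox gene, was 12.5-fold higher (-3.65, SE 0.35), Pitx1 8.22-fold (-3.04, SE 0.36), Nkx6-1, of the ventral neural tube, 5.87-fold (-2.55, SE 0.32), and Otx2, a forebrain and midbrain homeobox gene, 4.21-fold (-2.07, SE 0.32). Of 18099 genes tested, limma called 1145 changed, 638 higher in rostral and 507 higher in caudal pools, and 308 of them differed by at least 2-fold (182 rostral, 126 caudal). For 2264 genes (12.5%) the 4 arrays of 1 part all lay above the 4 of the other, against 2.86% by chance, and 1129 of the called genes did so. With the array's row on the slide as a block 1021 genes were called. Within the first slide row, with 2 pools of each part, limma called 0 genes (2385 at an unadjusted p below 0.05), and within the second it called 185 (2481). Without caudal pool 1 the count was 718 and without caudal pool 4 it was 752.

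The other rostral genes with the largest changes were Pmch, the precursor of melanin-concentrating hormone (3.47), the forebrain gene Fezf1 (3.23), Etv1 (2.56), Zic1 (2.53), the platelet chemokine gene Ppbp (2.48), Wnt8b (2.46) and the collagen gene Col25a1 (2.45). Pmch and Fezf1 were well above background in 1 of 4 caudal pools, and in the Feature Extraction processed signals, which carry no offset, their changes were 5.96 and 6.20, and that of Nkx2-1 was 3.58. Other probes gave 0.63 for Etv1 (adjusted p = 0.535), -0.13 for Zic1 (adjusted p = 0.666) and 0.23 for Col25a1 (adjusted p = 0.333), and the mean over probes was 1.36 for Wnt8b. Of these probes, that of Etv1 was well above background in 4 of 8 pools and those of Zic1 and Col25a1 in 8. The other Wnt8b probe in that mean was well above background in 2 of 8 pools and on 0 arrays for the reference. On the caudal side stood Pou4f2 (-2.78), the chemokine receptor gene Cxcr4 (-2.34), Gli3, of Hedgehog signalling (-2.30), Nkx2-9 (-2.24), Lyzl4 (-2.21, well above background in 2 of 4 rostral pools) and Pax8 (-2.09). Many of these genes were scarcer in the sorted cells than in the reference: of the 10 largest changes on each side, the mean ratio of the higher part lay below 0 for 7 rostral and 6 caudal genes. Pitx1 was among those above it, at 3.77 ± 0.06 in caudal and 0.74 ± 0.86 in rostral pools (log2 ratio to the reference, SD, n = 4). Of 621 genes at least 2-fold above the reference, 135 (21.7%) differed between the parts, 59 higher in rostral and 76 in caudal pools. Among 1678 genes at least 2-fold below it 210 (12.5%) differed, 114 rostral and 96 caudal, and of the 15800 between, 800 (5.06%).

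Several genes that define the dopaminergic neurons did not differ detectably between the parts. Th was at 3.39 ± 0.10 in rostral and 3.29 ± 0.08 in caudal pools (adjusted p = 0.44), Pitx3 at 3.58 ± 0.12 and 3.59 ± 0.10 (adjusted p = 0.997), and Nr4a2 at 3.78 ± 0.15 and 3.74 ± 0.09 (adjusted p = 0.883; log2 ratio to the reference, SD, n = 4). In the sample channel alone their changes were -0.30 (adjusted p = 0.115), -0.33 (adjusted p = 0.0515) and 0.13 (adjusted p = 0.752). Slc18a2 was higher in caudal pools, at 5.22 ± 0.10 against 4.66 ± 0.12 (adjusted p = 0.0078). Aldh1a1 was higher in rostral pools, at 5.91 ± 0.14 against 5.35 ± 0.14 (1.48-fold, adjusted p = 0.0066), and the change was 1.19 in the sample channel alone. Slc6a3 (0.24, adjusted p = 0.09) passed the test in the sample channel alone (0.70, adjusted p = 0.0064), and Ddc (0.20, adjusted p = 0.209) without rostral pool 4 (0.28, adjusted p = 0.0305), but another probe of Ddc gave -0.22 (adjusted p = 0.407) and the mean over probes -0.01 (adjusted p = 0.965). The change of Drd2 was 0.04 (adjusted p = 0.966). Of 12 genes of dopamine synthesis, transport and storage, 3 were higher in caudal and 0 in rostral pools, and adjusted over the list alone 4 and 2 (median 0.04, mean -0.02, camera direction down, adjusted p = 0.577). Among 16 midbrain dopaminergic transcription factors 2 were higher in rostral and 3 in caudal pools, and adjusted over the list alone 3 and 5 (median -0.01, adjusted p = 0.517). En2 (-0.90, SE 0.12) and En1 (-0.78, SE 0.15), engrailed genes of the midbrain and isthmus, were higher in caudal pools, and Pbx3 (0.75, SE 0.09) in rostral pools. With the replicate number as a block the adjusted p of En1 was 0.0507. Of 15 genes associated with the substantia nigra 5 were higher in rostral and 0 in caudal pools, and adjusted over the list alone 7 and 1 (median 0.19, adjusted p = 0.0762). Lmo3 (0.73, SE 0.12) and Zdhhc2 (0.72, SE 0.11) were among them, with 0.47 (adjusted p = 0.208) and 0.39 (adjusted p = 0.329) by other probes. This list passed the test without rostral pool 1 (adjusted p = 0.0361), caudal pool 2 (0.0471), rostral pool 2 (0.0426) or rostral pool 3 (0.0337), within the second slide row (0.0413), without an intensity trend (0.0123) and in the sample channel alone (0.0075), but not with an estimated correlation (0.614). Of 18 genes associated with the ventral tegmental area 2 were higher in rostral and 3 in caudal pools, and adjusted over the list alone 6 and 5 (median 0.03, mean -0.08, adjusted p = 0.979), camera putting it down and fry up. Cck was at 1.60 ± 0.78 in rostral and 2.56 ± 0.07 in caudal pools (adjusted p = 0.117), with a change of -1.23 (adjusted p = 0.0334) without rostral pool 2, -0.63 (adjusted p = 0.108) without rostral pool 3 and -1.48 (adjusted p = 0.0362) in the sample channel alone. Neither Calb1 (-0.24, adjusted p = 0.782) nor Sox6 (0.62, adjusted p = 0.177) passed the test. The change of Sox6 was 2.14 (adjusted p = 0.11) in the Feature Extraction processed signals and 0.38 (adjusted p = 0.241) without rostral pool 2.

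**Figure D2:**
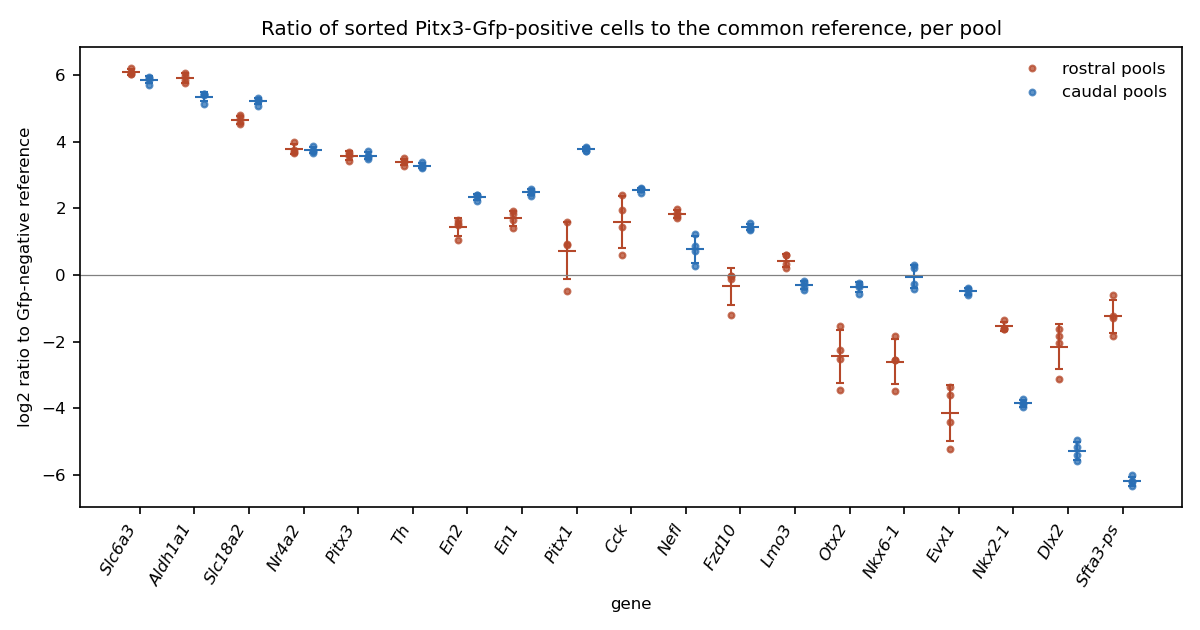
Log2 ratio of 19 genes to the Gfp-negative reference in rostral and caudal pools; each point is 1 pool, and bars give the mean ± SD (n = 4 pools per part). Th lies near 3.4 in rostral and 3.3 in caudal pools, while Pitx1 is at 0.74 ± 0.86 and 3.77 ± 0.06.

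Some genes of synaptic vesicles and neuronal maturation were higher in rostral pools. Of 26 tested, 12 were higher in rostral and 0 in caudal pools, and adjusted over the list alone 17 and 1 (median 0.31, camera adjusted p = 6.2e-08, and adjusted p = 0.0552 with an estimated correlation). Nefl, a neurofilament gene, was 2.07-fold higher (1.05, SE 0.17, adjusted p = 0.0079). Syn1, a synapsin (0.32, SE 0.06), and Rbfox3, a splicing factor gene of mature neurons (0.30, SE 0.06), also rose, and without a trend in the variance prior their adjusted p was 0.058 and 0.0571. Other probes of Rbfox3 gave 0.51 (adjusted p = 0.354) and 0.53 (adjusted p = 0.0821). The list's adjusted p was 7.7e-08 with the slide row as a block, 1.9e-05 within the first slide row and 0.00019 within the second. Of 12 pan-neuronal markers 0 were higher in rostral and 1 in caudal pools, the same adjusted over the list alone (median 0.09, adjusted p = 0.396). The 1 was Tubb3, neuronal beta-tubulin (-0.39, SE 0.05, adjusted p = 0.0019). Among 18 calcium-binding and calcium channel genes 2 were higher in rostral and 0 in caudal pools, and adjusted over the list alone 6 and 1 (median 0.21, adjusted p = 0.0762). Cacna1c, a channel subunit, changed by 0.71 (SE 0.14), with an adjusted p of 0.0516 without caudal pool 4. Of 23 cell cycle genes 2 were higher in rostral and 0 in caudal pools, the same adjusted over the list alone (median 0.23, adjusted p = 0.108). Of 36 oxidative phosphorylation genes limma called 0, also adjusted over the list alone, with 3 at an unadjusted p below 0.05 (median -0.01, mean 0.01, adjusted p = 0.963), camera putting the list down and fry up.

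**Figure D3:**
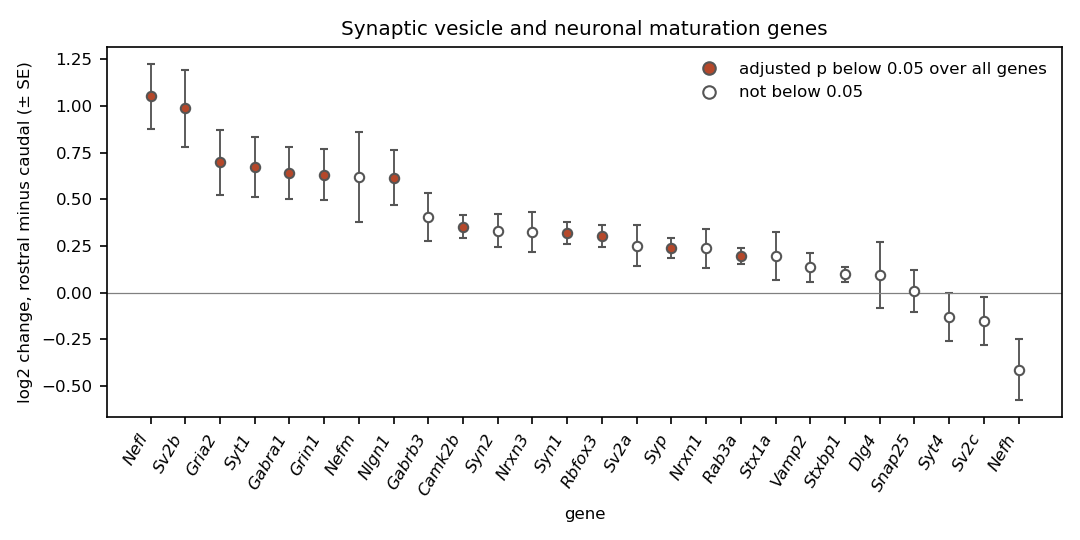
Log2 change between rostral and caudal pools of the 26 tested genes of synaptic vesicles and neuronal maturation; points give the change, bars its SE (n = 4 pools per part), and filled points passed limma's test over all genes at an adjusted p below 0.05. The 12 filled points all lie above 0, and the median of the list is 0.31.

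Guidance and signalling genes moved in both directions. Among 37 axon guidance and migration genes 9 were higher in rostral and 7 in caudal pools, and adjusted over the list alone 10 and 9 (median 0.11, adjusted p = 0.311). Sema3c, a secreted guidance cue, was 5.16-fold higher in rostral pools (2.37, SE 0.22; 1.46 as the mean over probes), the ephrin receptor gene Epha3 3.57-fold (1.84, SE 0.21) and Robo2, a Slit receptor, 2.54-fold (1.34, SE 0.14), whereas Cxcr4 and Ephb1 (-0.55, SE 0.07) were higher in caudal pools. The other probe of Sema3c was well above background in 3 of 8 pools. Of 25 Wnt pathway genes 5 were higher in rostral and 2 in caudal pools, and adjusted over the list alone 6 and 4 (median 0.06, adjusted p = 0.639). Wnt7b (1.40, SE 0.25), Sfrp2 (1.30, SE 0.14) and Rspo2 (1.23, SE 0.22) rose in rostral pools, and the receptor gene Fzd10 in caudal pools (-1.77, SE 0.24). Retinoic acid genes split 2 and 2 of 18, and adjusted over the list alone 2 and 3 (median -0.05, adjusted p = 0.517), with Cyp26b1 (-1.56, SE 0.29) and the retinal reductase gene Dhrs3 (-0.73, SE 0.10) higher in caudal pools. Of 17 isthmic and caudal genes 2 were higher in rostral and 4 in caudal pools, the same adjusted over the list alone (median -0.07, adjusted p = 0.128). Pax8, En1 and En2 were among those on the caudal side. Gbx2, a homeobox gene, was at least 2.88-fold higher in rostral pools in the sample channel, being not well above background in any caudal pool. Etv5, also higher in rostral pools, changed by 1.12 (SE 0.14). Of 19 diencephalic and rostral genes 6 were higher in rostral and 2 in caudal pools, and adjusted over the list alone 7 and 3 (median 0.08, adjusted p = 0.128). Six6, of the hypothalamus and eye, was at least 3.76-fold higher in rostral pools in the sample channel, and Lhx9 was at -1.60 (SE 0.20), with -0.42 (adjusted p = 0.477) by another probe. That probe of Lhx9 was well above background in 4 of 8 pools. Parkinson's disease genes split 2 rostral and 1 caudal of 21, the same adjusted over the list alone (median 0.01, adjusted p = 0.639). Sncaip, the synphilin gene, was 1.38-fold higher in rostral pools (0.46, SE 0.09), with an adjusted p of 0.0503 without caudal pool 1. Neuropeptide genes were higher in caudal pools for 1 of 16 and in rostral for 0, and adjusted over the list alone 4 and 2 (median 0.04, mean -0.11, camera direction down, adjusted p = 0.645). The 1 was Sst, somatostatin (-1.06, SE 0.13).

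Markers of other cell types also differed in part. GABAergic markers were higher in rostral pools for 4 of 11 and in caudal pools for 2, and adjusted over the list alone 6 and 3 (median 0.46, adjusted p = 0.128). Dlx1 was at least 2.89-fold higher in rostral pools in the sample channel, with no caudal pool well above background, and Tal2 was higher in caudal pools (-1.79, SE 0.16). Glutamatergic and red nucleus markers split 2 rostral and 3 caudal of 9, and adjusted over the list alone 2 and 4 (median -0.18, adjusted p = 0.396), with Lhx2 at -1.73 (SE 0.17). Motor and oculomotor markers split 1 and 1 of 9, and adjusted over the list alone 2 and 1 (median -0.19, adjusted p = 0.639), with Isl1 at 0.65 (SE 0.12). Of 6 serotonergic markers 1 was higher in caudal pools and 0 in rostral, and adjusted over the list alone 2 and 0 (median -0.30, adjusted p = 0.233), that gene being Fev (-0.82, SE 0.14). Of 6 oligodendrocyte precursor markers 1 was higher in rostral pools and 0 in caudal, and adjusted over the list alone 2 and 0 (median 0.23, adjusted p = 0.128), that gene being Nkx2-2 (1.05, SE 0.14), with 1.01 (adjusted p = 0.0942) by another probe. Progenitor and radial glia markers split 2 and 2 of 17, the same adjusted over the list alone (median -0.06, mean 0.02, camera direction down, adjusted p = 0.672). Ptprz1 was at 1.01 (SE 0.16), with 0.90 (unadjusted p = 0.0012) and 0.58 (adjusted p = 0.581) by other probes. The probe at 0.90 was well above background in all 8 pools and that at 0.58 in 4. The caudal pair were Vim (-0.63, SE 0.11) and Msx1 (-0.92, SE 0.17). With the replicate number as a block the adjusted p of Vim was 0.056 and that of Msx1 0.0587. Of 11 dissociation stress markers 1 was higher in caudal pools, Btg2 (-1.25, SE 0.16), and 0 in rostral, and adjusted over the list alone 2 and 1 (median 0.25, adjusted p = 0.577). Of 11 microglia markers 1 was higher in rostral pools and 0 in caudal, the same adjusted over the list alone (median -0.10, mean 0.03, adjusted p = 0.966), camera putting the list down and fry up. That gene, Mrc1, was at 1.86 ± 0.43 in rostral and -0.21 ± 0.44 in caudal pools. Limma called 0 of 10 endothelial markers (median 0.05, mean -0.02, camera direction up, adjusted p = 0.921), 0 of 11 erythroid markers (median 0.18, adjusted p = 0.577) and 0 of 10 pericyte and mesenchyme markers (median 0.36, adjusted p = 0.517). At an unadjusted p below 0.05 there were 2, 0 and 2 of these, and adjusted over the list alone 0, 0 and 2 (1 rostral, 1 caudal). Ppbp, a gene of platelets, was at 3.12 ± 0.36 in rostral and 0.64 ± 1.06 in caudal pools.

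Camera thus called 1 of 27 lists between the parts, and 0 with an estimated correlation (1 at an unadjusted p below 0.05). Fry, whose PValue tests net movement 1 way, called 5: the synaptic, substantia nigra, isthmic, axon guidance and glutamatergic lists. Its PValue.Mixed, which tests change in either direction, called 24, and neither compares a list with other genes. Without rostral pool 3 camera called 5 lists, without rostral pool 2 or caudal pool 2 it called 4, and without rostral pool 1 it called 2.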

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

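The tests of cell cycle genes against the synaptic list and of erythroid markers were chosen only after the values they measure were seen, and the synaptic list's test on the sample channel alone, the comparisons of that list's p and of the smallest list p with other splits and the platelet marker set were chosen after the pattern they bear on had been noticed.

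Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one between rostral and caudal pools, called as many genes. It called 1145, against at most 1 in the others and 0 in the split by slide row. This argues against chance for the number of genes, but a rank of 1 in 35 is the most that 8 arrays can give. Each other split mixes rostral and caudal pools, which widens the spread within its groups. The size of the margin is thus no measure of the evidence. If the pools of 1 part had carried more Gfp-negative cells, genes above the reference would be diluted there as a set and genes below it raised. Over all genes at least 2-fold above the reference the median change was 0.046 (quartiles -0.27 to 0.32, with 43.7% of called genes higher in rostral pools), and over all genes at least 2-fold below it 0.014 (quartiles -0.22 to 0.33, 54.3%), which argues against unequal carry-over as the whole source. Equal shares of carried-over cells of different local kinds may still account for called genes below the reference, whose median ratio in the higher part was -1.25; this cannot be told apart from expression in the sorted neurons, because the Gfp-negative cells of each part were not measured apart. A difference between the dopaminergic neurons of the 2 parts stays open as the explanation the design names, untested beyond this.

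The synaptic and neuronal maturation list, higher in rostral pools, had a p of 2.3e-09, the smallest of the 27 lists. Since the list was picked for that, the smallest p over all lists was taken in each split: 3 of the 35, the real one included, gave 1 at least as small (1.0e-14 at the lowest elsewhere), both others through the microglia list, so chance is not excluded for this shift. For the synaptic list taken alone, only the real split gave a p as small (3.2e-06 at the lowest elsewhere), which does not allow for the choice among 27 lists. Nor is it for the number of lists: the real split called 1, another called 5, and 24 of 35 gave at least as many, since camera at its preset correlation called at least 1 list in 23 of the other splits. More dividing cells in caudal pools would put cell cycle genes higher there, yet their median change was 0.23 with 18 of 23 genes on the rostral side. This leaves open undifferentiated cells that no longer divide, as progenitor and radial glia markers went both ways (median -0.06). Vim (-0.63) and Msx1 (-0.92) were higher in caudal pools, and Ptprz1 (1.01) and Hopx (0.80) in rostral pools. An effect of the reference channel or of loess is argued against by the sample channel alone, where the list's camera adjusted p was 1.1e-09. It was 4.0e-08 in the Feature Extraction processed signals, but these keep the reference channel and a lowess step, so they cannot decide this. Over the camera settings run at the preset correlation, the adjusted p reached 0.00019 at most, and with an estimated correlation it was 0.0552. A candidate explanation is that rostral neurons are further along in maturation at this age, which no value here tests directly.

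Platelet genes stood above the reference and higher in rostral pools: Ppbp, Pf4, Gp1ba, Treml1 and Alox12, chosen after their values were seen, had a median change of 2.12. Of 11 further platelet markers, written down before their values were looked at, 9 were tested, and their median change was 0.47 with a median ratio of 0.32 to the reference and 7 of 9 higher in rostral pools, so platelets or megakaryocytes carried through the Gfp sort, more of them in rostral pools, may account for the pattern but cannot be told apart from other sources, both values lying between the bounds set beforehand. Itgb3 (1.62, adjusted p = 0.0107, and 1.05 with adjusted p = 0.125 by another probe) and Clec1b (1.62, adjusted p = 0.0375, and by other probes 0.31 with adjusted p = 0.342 and 1.58 with adjusted p = 0.0241) were called. Clec1b lost its call in the Feature Extraction processed signals (2.87, adjusted p = 0.101), without a trend in the variance prior (0.0619), with the replicate number as a block (0.0628), within either slide row (0.409 and 0.0975) and without caudal pool 2 (0.0748), 3 (0.0669) or 4 (0.0863) or rostral pool 2 (0.0907), 3 (0.0624) or 4 (0.0952). Whole blood carried along is argued against by erythroid markers, whose median ratio was -3.68 with 12 of 12 below the reference. Expression of these genes by the dopaminergic neurons themselves was not tested.

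Single pools lay far from the others of their group, as measured by the gap to the nearest pool over the whole range of the group. In groups of 4 this ratio passed its critical value for Pmch in rostral pools (0.835, pool 2 at -2.83 against -1.53 to -1.28), Dlx1 in rostral pools (0.836, pool 2 at -1.78), Fzd10 in rostral pools (0.907, pool 3 at -1.19 against -0.13 to -0.02), Ptprz1 in rostral pools (0.861, pool 3 at -0.29), Bdnf in rostral pools (0.923, pool 3 at 3.06 against 2.50 to 2.54) and Dhrs3 in rostral pools (0.886, pool 4 at -0.53). It also did so for Aldh1a1 in caudal pools (0.876, pool 2 at 5.14 against 5.39 to 5.43), Sst in caudal pools (0.862, pool 2 at -2.65), Cck in caudal pools (0.852, pool 2 at 2.46) and Drd2 in caudal pools (0.839, pool 1 at 2.41 against 1.91 to 1.99). Over all 8 pools it did so for Kcnj8 (0.531, rostral pool 2 at -3.31), Ncam1 (0.533, caudal pool 2 at -0.77), Cdh5 (0.555, rostral pool 3 at -2.98), Crym (0.529, caudal pool 2 at -2.89) and Irx3 (0.690, caudal pool 2 at -2.83). Among list means, the pericyte and mesenchyme list stood out in rostral pools (0.918, pool 2 at -1.17 against -2.75 to -2.62), as did the calcium list in rostral pools (0.878, pool 1 at 0.80), the Wnt list in caudal pools (0.916, pool 2 at -1.19) and the oligodendrocyte precursor list in caudal pools (0.841, pool 4 at -3.76). Chance marks about 1 in 20 groups; here 10 of 154 gene groups of 4 (6.49%), 5 of 66 genes over 8 pools (7.58%) and 4 of 54 list means (7.41%) were marked, 7 of them for caudal pool 2.

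For 6 named genes every rostral pool lay on the other side of the reference from every caudal pool, and limma called each difference. Lmo3 (0.73), Wnt7b (1.40), Rspo2 (1.23) and Sncaip (0.46) were above the reference in rostral and below it in caudal pools. Fzd10 (-1.77) and Msx1 (-0.92) were the other way round. The reference carried the same dye on every array, so any dye effect is part of each ratio. The side of the reference is thus uncertain for mean ratios near 0, such as those of Sncaip (-0.09) and Msx1 (0.22) in caudal pools.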

How the results depend on the processing

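The fits within 1 slide row, camera without an intensity trend and the list tests with a slide row block or on the sample channel alone were chosen only after the results had been seen. For genes changed between rostral and caudal pools, 1145 in the report, settings other than those named next gave 827 to 1170. Each probe alone gave 1236 probes (968 genes). A minimum log2 change of 1 left 308 by construction, the first slide row alone gave 0 (2385 at an unadjusted p below 0.05) and the second 185 (2481), each with 2 pools per part. Leaving out 1 pool gave 718 (without caudal pool 1) to 1013, and 752 without caudal pool 4; fewer arrays lower the count by construction. With the replicate number as a block, a paired fit, 724 genes were called, 681 of them shared. Deviations of same-numbered pools correlated at 0.02, -0.01, -0.07 and -0.02, and those of other pairs at -0.097 to 0.105. This gave no sign of pairing, but the labels do not say whether equal numbers share embryos, so pairing stays undecided. For Gfp-positive against Gfp-negative cells, 13287 genes in the report, each probe alone gave 25771 probes (13941 genes), a minimum log2 change of 1 left 2429 by construction, leaving out 1 pool gave 12641 to 12902, the replicate block gave 12889, and the others gave 10221 to 14497.

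Camera called 1 list between the parts, 0 with an estimated correlation (1 at an unadjusted p below 0.05), 3 and 5 within the first and second slide row, 2 without an intensity trend, 3 in the sample channel alone, 1 to 5 without 1 pool and 1 with the replicate block; fry called 5 in 1 direction and 24 as mixed. In the Gfp comparison it called 19, and 0 with an estimated correlation (11 at an unadjusted p below 0.05). It called 18 to 20 without 1 pool and 18 with the replicate block, and fry called 24 and 26. A higher estimated correlation was not why the Wnt and transcription factor lists lost their call, and the cause was otherwise not tested.

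Of 2971 values of 134 named genes between the parts, 2684 kept direction and call, 266 kept direction and lost the call (138 within 1 slide row, 73 on leaving out 1 pool), 19 gained it and 2 reversed, where reversed means a change of sign with a call in either setting. The reversals came from other probes of Zic1 (-0.13) and Myt1l (-0.025). A further probe of Myt1l gave 0.53 (unadjusted p = 0.00046), near the 0.46 of the probe used. In the Gfp comparison 2461 of 2471 values of 122 genes kept both, 1 lost and 4 gained the call, and 5 reversed. These were Ncam1 in the Feature Extraction processed signals (0.040) and by another probe (0.37), and other probes of Nrxn3 (-0.18), Ndufa5 (0.089) and Calb1 (0.25). The cause was not tested. For that Calb1 probe the reference was well above background on 0 arrays, so its value does not measure a reversal.

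Not run were the authors' processed values, whose columns match no sample, a turned dye sign, since all arrays correlate positively, and a scan block, there being 1 scan. Aquantile leaves ratios unchanged by construction and so tests nothing. The dim genes Pmch, Fezf1, Six6, Gbx2 and Dlx1 changed more in the Feature Extraction processed signals, which differ in background correction, detrending, dye normalization and offset at once, and which of these matters was not tested.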

Other observations

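The tests of X-linked genes below were set before their values were seen, but the second gene set was chosen only after the first result, and the genes of the first paragraph were chosen after their values were seen.

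Among genes at least 2-fold above the Gfp-negative reference, 51 also differed at least 2-fold between the parts, 22 higher in rostral and 29 in caudal pools. The 22 include the platelet genes Ppbp, Pf4, Gp1ba, Treml1 and Alox12, for which carried-over platelets were left open above. Npy1r, a neuropeptide Y receptor gene, was 3.79-fold higher in rostral pools (log2 change 1.92, SE 0.29, adjusted p = 0.0056, n = 4 and 4), and Bdnf, a neurotrophin gene, 2.25-fold (1.17, SE 0.18, adjusted p = 0.0062), at 2.66 ± 0.27 in rostral and 1.49 ± 0.31 in caudal pools (log2 ratio to the reference, SD). Gipr, the receptor of an incretin hormone, was 3.54-fold higher in caudal pools (-1.82, SE 0.23, adjusted p = 0.0024), and Mc3r, a melanocortin receptor gene, 3.12-fold (-1.64, SE 0.25, adjusted p = 0.0058). Frem1, an extracellular matrix gene, changed by -1.28 (SE 0.12, adjusted p = 0.00066) and Pcsk6, a proprotein convertase gene, by -1.10 (SE 0.16, adjusted p = 0.0048), both higher in caudal pools. Npy1r, Bdnf, Gipr, Mc3r, Frem1 and Pcsk6 all kept their call in each fit without 1 pool. None of these 6 passed the test within the first slide row alone. Limma called 0 of 18098 genes there, so this says nothing particular to the 6.

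Sex-linked transcripts differed between pools of 1 part. Xist, the transcript of the inactive X chromosome, was at -1.45 in rostral pool 2 against 0.33 to 0.51 in the other rostral pools, and the mean of the Y-linked genes Ddx3y and Eif2s3y was at 1.14 there and at -1.55 in rostral pool 3 (log2 ratios to the reference). Over the 8 pools Xist and the Y-linked mean were related inversely (Pearson r = -0.82, exact permutation p = 0.0102; Spearman rho = -0.67, exact p = 0.0831), with adjusted p of 0.0295 and 0.125 over the 3 relations in this family. Without rostral pools 2 and 3, the farthest from the median, r was -0.69 (exact p = 0.168, 6 pools).

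A candidate explanation is that the pools hold different shares of male and female embryos. If so, X-linked genes that escape inactivation should fall where Y-linked genes rise. The mean of Kdm6a, Kdm5c, Eif2s3x and Ddx3x did the opposite (r = 0.81, exact p = 0.0197, adjusted p = 0.0295; rho = 0.81, exact p = 0.0218, adjusted p = 0.0653; r = 0.95, exact p = 0.00972 without rostral pools 2 and 3), which on its face counts against it. All 4 are X copies of Y-linked genes, and Eif2s3x alone followed the Y-linked mean at r = 0.96 (exact p = 0.00064, adjusted p = 0.0052 over 8 genes) while Kdm5c went the other way (r = -0.79, exact p = 0.0139, adjusted p = 0.0557), so probes that read both copies could set this value and the test decides little. The mean of Pbdc1, Jpx, Ftx and 5530601H04Rik, which have no Y copy, gave r = -0.26 (exact p = 0.535; rho = -0.24, exact p = 0.582; r = -0.50, exact p = 0.235 without rostral pools 2 and 3). The explanation thus stays open, and the sexes of the embryos were not analysed here.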
